A study of Mus musculus with 2 samples.

How the data were processed

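Live EpCAM-positive colonic epithelial cells were sorted by flow cytometry and taken through 10x Genomics 3' single-cell RNA sequencing, per the labels' protocols. The series holds 2 libraries, 1 of genotype Mettl14 WT and 1 of Mettl14 KO. The labels do not say how many animals each library pooled. The authors deposited a filtered matrix of UMI counts per gene and cell, which held whole numbers for 17829 gene symbols and 7863 cells, and a table that gives each cell's library and a cluster number. Per the submitters' processing notes, bcl2fastq and Cell Ranger with mm10 were used, with no versions stated. The filter and the clustering method are not stated. In the counts no cell exceeded a mitochondrial share of 20%, and the shallowest cell held 792 UMIs.

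UMI counts were summed over the cells of a library, or of a cluster and library, and divided by the summed total to give CPM. Ratios are log2 of KO CPM over WT CPM. Their 95% intervals are exact conditional binomial intervals, those of CPM are exact Poisson intervals and those of cell shares are exact Clopper-Pearson intervals. All cover counting error only, and not variation between animals or preparations. With 1 library per genotype no test and no p-value is given, since neither cells nor genes are replicates. A gene was measured with at least 50 UMIs over both libraries. Where a library had 0 counts, the fold was computed against a floor of 3 counts over the group and written as a lower bound, and a share of 0 cells is given an upper limit of 3 cells.

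Choices made before the data were examined were the rule for named genes, the gene lists, the cell type markers and the main settings. Named genes were the 10 highest and 10 lowest over all cells by the interval bound nearest to 0, with at least 20 CPM in a library, and the 5 highest and 5 lowest in each of the 4 largest classes. Up to 4 genes per list were named by the same bound. Always named were Mettl14, Mettl3, Nfkbia, Tnf, Muc2, Lgr5, Mki67 and Car1, and markers of the classes could be named. Predicted genes were counted and not named. Some genes that met these rules are not reported here. The same ranking without the enzyme-rich cells, the shares of UMIs held by few cells and the genes that lead cluster 0 without the enzyme-rich cells were chosen after seeing the data.

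The 24 lists, several of which share genes, covered m6A factors, NF-κB, TNF death pathway, p53, interferon, both MHC classes, antimicrobial, mucus, colonocyte transport, stem and Wnt, S phase, G2 and M phase, junctions, stress responses, immediate early genes, regeneration, suckling genes, fatty acid oxidation, nuclear and mitochondrial respiratory genes, ribosomal proteins, xenobiotic handling and sex-linked genes. Each list's median log2 ratio was ranked among 10000 random lists of the same size drawn from 20 expression bins. The percentile describes these libraries and is no test. Members were counted as higher or lower at 1.5-fold with an interval that excludes equal levels.

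Each of the authors' 7 clusters was named after the marker list with the highest mean z score of log CPM if at least 3 of its markers were detected and its 10 leading genes did not hold more markers of another class. Clusters of very low UMI counts with no own marker among these genes stayed unnamed, as did, by a rule set after seeing the data, clusters with at least 5 pancreatic enzyme genes among them. Classes with at least 50 cells in each library were compared. A class-standardised ratio is the mean of the log2 ratios of the 5 classes with equal weights. Cells with at least 3 Xist UMIs and no UMI of 4 Y-linked genes were taken as female, and cells with a Y-linked UMI and no Xist UMI as male. Cells in which 11 pancreatic enzyme genes made up at least 1% of the UMIs were marked as enzyme-rich.

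Own clusterings used log-normalised counts, 2000 variable genes without mitochondrial, ribosomal, haemoglobin and sex-linked genes, 30 principal components, 15 neighbours and Leiden at resolutions 0.5 and 2, or 1 for cells thinned to 3000 UMIs. One added clustering, at resolution 0.5, scaled each gene within its library and left out 7544 genes at least 1.5-fold apart. No doublets were removed. The doublet score of scanpy marked 0 WT cells and 686 KO cells (18.8%), so it had not worked evenly and was not used. Cells with both Xist and Y-linked UMIs (327 WT cells, 7.77%, and 283 KO cells, 7.75%) were left out instead as an alternative. Gene positions and exon numbers come from the GENCODE vM21 annotation of GRCm38, and positions are counted from 1.

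Alternatives numbered 23 fixed in advance and 13 added after seeing the data. They changed the scaling, the gene filter, the cells kept, the weight of each cell, depth, clustering, sex and random lists. On simulated counts for 13334 genes, in which 100 genes differed 2-fold and 100 differed 4-fold between libraries of the real sizes, 98% and 99% were recovered with an interval that excluded equal levels, and 95.8% of all intervals held the true ratio. These counts were drawn per library from the Poisson model that the intervals assume, without variation between cells. They check the computation and not how the intervals behave for UMIs clumped in few cells. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, sklearn 1.9.0 and matplotlib 3.10.9.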

Results

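Single-cell 3' RNA profiles were collected from live EpCAM-positive colonic epithelial cells of C57BL/6 mice labelled Mettl14 WT or Mettl14 KO. Mettl14 encodes a subunit of the enzyme complex that writes m6A on RNA. There was 1 library per genotype, and the series text places the cells at 2 weeks without saying from when. The Mettl14 WT library held 4210 cells with 60205658 UMIs and a median of 12094 UMIs and 3189 genes per cell. The Mettl14 KO library held 3653 cells with 37635762 UMIs and a median of 9119 UMIs and 2751 genes per cell. The median mitochondrial share of UMIs was 11.9% and 11.6%. With 1 library on each side, no difference has a replicate check. Each value below compares these libraries, and its 95% interval covers counting error only. Ratios are log2 of KO CPM over WT CPM, and in brackets a ratio is followed by its interval.

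The first comparison asks whether the targeted gene differed between the libraries. Mettl14 (chromosome 3, 123368297 to 123386108, minus strand, GRCm38) was lower in the KO library, with 201 UMIs against 632, or 5.34 against 10.5 CPM, a log2 ratio of −0.97 (−1.21 to −0.74). The ratio was −1.43 (−2.17 to −0.75) in colonocyte-like cells, −1.11 (−1.54 to −0.70) in cycling-like cells and −1.09 (−1.60 to −0.61) in goblet-like cells, where clusters 1 and 2 alone gave −0.97 (−1.58 to −0.38) and −1.65 (−2.72 to −0.71). In cluster 0 it was −0.36 (−0.83 to 0.10) and in enteroendocrine-like cells −0.39 (−1.64 to 0.81), differences not detectable at this depth. At least 1 Mettl14 UMI was found in 13.4% of WT cells (exact interval 12.4 to 14.5) and 5.28% of KO cells (4.58 to 6.06). With every cell thinned to 3000 UMIs these shares were 3.05% and 1.77%, after 172 WT and 97 KO cells of lower depth were left out. No cell type is known to lack Mettl14, so no background share can be set beside them. The tags come from the transcript's 3' end, whose last exon lies at 123368297 to 123369690, and neither the labels nor the series text say which exons were deleted. If these tags lie outside the deleted part, the level checks nothing about the label. Mettl3, the catalytic partner of Mettl14, was lower as well, at 7.49 against 13.2 CPM with a log2 ratio of −0.82 (−1.02 to −0.63).

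Among other members of the m6A list, which covers writers, readers and erasers, the readers Ythdf2 and Ythdf1 and the writer subunit Rbm15 were higher in the KO library, with log2 ratios of 1.32 (1.26 to 1.37), 0.84 (0.76 to 0.92) and 1.21 (1.12 to 1.30). Of the list's 21 measured genes, 3 were at least 1.5-fold higher, 2 at least 1.5-fold lower and 16 neither. Its median was 0.15, at percentile 89.9 among 10000 random lists of the same size and expression. In all lists described here, a member counts as higher or lower only if its interval also excludes equal levels.

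The second comparison asks which transcripts differed over all cells. By the interval bound, the genes highest in the KO library were the carboxylesterase gene Ces1c, with 1728 UMIs against 7 (8.63, 7.58 to 9.94), and Msln, with 818 against 2 (9.35, 7.50 to 12.40). Both ratios rest on very few WT counts, and in the KO library 18.8% of cells held a Ces1c UMI and 7.12% a Msln UMI. Ubd, a ubiquitin-like modifier induced by cytokines, stood at 107 against 0.747 CPM (7.17, 6.74 to 7.62). Slpi, a secreted protease inhibitor of mucosal surfaces, stood at 155.7 against 1.495 CPM (6.70, 6.40 to 7.02). Ccl20, a chemokine that attracts lymphocytes and dendritic cells, stood at 142 against 6.18 CPM (4.53, 4.38 to 4.68). The other genes among the 10 highest were Ncf4, a subunit of the phagocyte NADPH oxidase (6.61, 6.06 to 7.23), the class I-like gene H2-M2 (6.11, 5.50 to 6.79), Il4i1 (5.27, 4.78 to 5.80), Spib, a transcription factor of M cells and B cells (4.97, 4.52 to 5.47), and Serpina10 (4.93, 4.70 to 5.17). Ces1c and H2-M2 belong to families of near-identical genes, so reads may have been split or misassigned among relatives. In the 1060 WT and 1176 KO cells with at least 1000 UMIs and at most 10% mitochondrial UMIs, the ratios of Msln, Ncf4, Spib and Ccl20 were smaller, at 5.76, 5.45, 2.93 and 2.96. With equal weight for each class those of Ces1c, Msln, H2-M2, Il4i1 and Ccl20 were 7.31, 6.56, 5.44, 3.78 and 3.61, while Ubd and Spib stood at 7.13 and 4.76. At Leiden resolution 0.5, Ccl20, Spib, Il4i1, Msln, H2-M2 and Ubd were among the leading genes of a cluster of 0 WT and 366 KO cells. Their ratios over all cells may thus also carry a difference in kinds of cells. Slpi stood at 5.75 by the mean of per-cell CPM, and at 7.98 in cells with Xist and no Y-linked UMI against 5.53 in cells with the reverse. Ccl20 lies on chromosome 1 at 83116766 to 83119167, Slpi on chromosome 2 at 164354070 to 164389095 and Ubd on chromosome 17 at 37193892 to 37196095.

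Of 6249 genes with at least 50 UMIs and at least 20 CPM in a library, 376 (6.02%) were at least 2-fold higher and 176 (2.82%) at least 2-fold lower in the KO library, as a rule of size and not a test. The median of all 13334 measured genes was −0.04. Of the genes past 2-fold, 68.1% were higher, and 56.9% when both the scaling and the 20 CPM minimum left out mitochondrial, ribosomal-protein and haemoglobin genes.

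Genes lower in the KO library were led by transcripts of pancreatic digestive enzymes, which lay in a few WT cells. Ctrb1, encoding chymotrypsinogen, had 32518 UMIs in the WT library and 0 in the KO library, which makes it at least 6776-fold lower when the KO count is set at a floor of 3. Cpb1, Cela3b, Cpa1, Try4 and Cel also had 0 KO UMIs, with bounds from at least 1323-fold for Cpb1 to at least 377-fold for Cel, while Pnliprp1 had 11 against 13486 (−9.58, −10.58 to −8.74). Together 11 such enzyme genes had 83696 UMIs in the WT library, of which 83166 lay in 33 cells, all in cluster 0. Reg2, another gene expressed in the pancreas (at least 403-fold), and 1 predicted gene completed this group. Defb50, the remaining gene among the 10 lowest, had 1947 WT UMIs, of which 98.9% lay in 10 cells, and 0 KO UMIs. Try4, Reg2 and Defb50 belong to multigene families and are uncertain for that reason.

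Without those 33 cells, Lgr5, the marker of intestinal stem cells, was among the genes furthest below the WT level, at 6.32 against 70.5 CPM (−3.48, −3.67 to −3.29), and over all cells its ratio was −4.29 (−4.67 to −3.94) in female and −2.88 (−3.22 to −2.56) in male cells, taken by Xist and Y-linked UMIs. The mitochondrial urea cycle enzyme gene Cps1 (−4.28, −4.60 to −3.98), the metallothionein gene Mt3 (−3.60, −3.93 to −3.29) and the folate receptor gene Folr1 (−3.57, −3.95 to −3.21) were also lower. Fosb, an immediate early transcription factor (−3.34, −3.48 to −3.21), Ppic (−3.13, −3.40 to −2.87), and Timp3, an inhibitor of matrix proteases (−2.83, −3.01 to −2.67), followed. Spp1, encoding osteopontin, had 9 against 1972 UMIs (−7.11, −8.24 to −6.18), and 98.9% of its WT UMIs lay in 23 cells. Lgr5 lies on chromosome 10 at 115450311 to 115587780.

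Inflammatory and death-related gene lists had medians above those of nearly all random lists in the KO library. For NF-κB targets and regulators the median was 0.89 (percentile 100), with 14 of 26 genes higher, 2 lower and 10 neither. Its largest differences were Ccl20, Tnfaip2 (3.32, 2.46 to 4.29) and Nfkb2 (2.11, 1.93 to 2.29), with Traf1 lower (−2.52, −3.18 to −1.92). Nfkbia, which encodes the inhibitor IκBα and is itself an NF-κB target, stood at 207.2 against 73.4 CPM (1.497, 1.44 to 1.55). For the interferon response list the median was 0.78 (percentile 100), with 27 of 41 genes higher and 1 lower, led by Rtp4 (3.72, 3.49 to 3.95), Isg15 (3.43, 3.20 to 3.67), Ifi44 (2.88, 2.41 to 3.39) and Oasl2 (2.29, 2.03 to 2.56). Tnf, the gene of the cytokine TNF, had 281 UMIs against 73 (2.62, 2.25 to 3.01). It belongs to the apoptosis and TNF death list, whose median was 0.27 (percentile 99.6), with 10 of 35 genes higher, among them Bax (1.46, 1.41 to 1.51) and Tnfrsf1b (1.77, 1.55 to 1.99), and 5 lower, among them Gsdmc4 (−1.84, −1.94 to −1.75), a member of a family of close copies. Of 24 p53 targets, 11 were higher and 1 lower (median 0.35, percentile 99.7), with Phlda3 at 3.59 (3.40 to 3.79), Gdf15 at 2.60 (2.40 to 2.80) and Eda2r at 2.31 (1.93 to 2.71).

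Stress and repair lists held members on both sides. In the unfolded protein and integrated stress response list 8 of 29 genes were higher and 3 lower (median 0.24, percentile 98.3). Chac1 (5.18, 4.39 to 6.11), Trib3 (4.92, 3.83 to 6.26) and the chaperone gene Hspa5 (1.29, 1.27 to 1.32) were higher, and Atf3 (−3.14, −3.53 to −2.76) was lower. In the regeneration and fetal-like epithelium list 8 of 22 genes were higher, including Ly6a (3.09, 3.004 to 3.18), and 7 lower, including Cyr61 (−2.83, −3.10 to −2.57), with a median of 0.32 (percentile 99.2). The immediate early and dissociation list was lower, with 15 of 30 genes lower and 4 higher (median −0.60, percentile 0). Among its lowest members, Dusp1 had a log2 ratio of −2.83 (−3.07 to −2.61).

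In the mucus and goblet secretory list 9 of 27 genes were higher and 3 lower (median 0.37, percentile 99.9). Its median was 0.18 in goblet-like cells and 0.84 in cluster 0. Tff3, the goblet cell trefoil peptide, stood at 7282 against 1234 CPM (2.56, 2.55 to 2.57). The lectin gene Zg16 (2.03, 2.004 to 2.06), Retnlb (1.98, 1.96 to 2.01) and the membrane mucin gene Muc1 (2.73, 2.62 to 2.84) were higher too. Muc2, the gel-forming mucin, stood at 1860 against 2049 CPM (−0.14, −0.15 to −0.13), and Spink4, a goblet cell marker, was lower at −1.37 (−1.38 to −1.36). The antimicrobial and acute phase list was split, with 11 of 24 genes higher and 10 lower (median 0.16, percentile 91.2). Its median was 0.68 with equal weight for each class, 0.96 in female and 0.75 in male cells, and −0.15 in cluster 0 against 0.72 to 1.09 in the other 4 classes. Beside Slpi, Saa3 was higher (3.05, 2.63 to 3.49), while Ang4 (−2.80, −2.96 to −2.64) and Reg1 (−8.30, −8.75 to −7.89) were lower. Of the WT library's Reg1 UMIs, 99.3% lay in 33 cells with at least 10 UMIs, and the list's median was 0.42 without the enzyme-rich cells and 0.998 without the immune gene cluster described below. Saa3, Ang4 and Reg1 have close copies.

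Stem and Wnt target genes were lower: 11 of 27 were lower and 2 higher, with a median of −0.49 (percentile 0). Besides Lgr5, the stem cell gene Smoc2 (−1.72, −1.88 to −1.56) and Hopx (−1.56, −1.63 to −1.49) were lower, while Olfm4 had 70 UMIs against 8 (3.81, 2.75 to 5.07). Proliferation genes did not move as a block. Of 30 S phase genes, 9 were lower, such as Cdca7 (−1.09, −1.18 to −1.004), Ccne2 (−0.98, −1.24 to −0.73) and Hells (−0.83, −0.92 to −0.73), and 1, Fen1, was higher (1.32, 1.22 to 1.42), giving a median of −0.43 (percentile 0), which was −0.20 in male cells and 0.10 in colonocyte-like cells. Among 39 G2 and M phase genes, 4 were higher and 4 lower (median −0.12, percentile 12.4), and Mki67 stood at 182 against 117 CPM (0.63, 0.58 to 0.68). That list's median was 0.03 in cells with a Y-linked UMI and no Xist, 0.50 in colonocyte-like and −0.67 in enteroendocrine-like cells.

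Absorptive functions were uneven. Of 37 colonocyte transport and differentiation genes, 11 were higher and 6 lower. Their median of 0.04 (percentile 73.6) became −0.03 under CPM without mitochondrial and ribosomal-protein genes, which shifts every gene by −0.07. With equal weight for each class it was 0.24, and it was above 0 in 4 of 5 classes. Car1, a carbonic anhydrase of the proximal colon, was higher at 72.9 against 28.5 CPM (1.36, 1.27 to 1.44), as was the sodium channel subunit gene Scnn1b (2.95, 2.75 to 3.16), and the water channel gene Aqp8 (−2.36, −2.56 to −2.17) and the guanylin gene Guca2a (−2.005, −2.05 to −1.96) were lower. Genes that handle bile acids, retinoids and xenobiotics were lower in 15 of 33 cases and higher in 3 (median −0.57, percentile 0), with the cytochrome P450 genes Cyp2c55 (−2.56, −2.79 to −2.34), Cyp2s1 (−2.30, −2.62 to −1.997) and Cyp2d26 (−2.25, −2.53 to −1.98) among the lowest. The median of that list was −0.25 when every cell class had equal weight. Aqp8 and Cyp2c55 were among the leading genes of a cluster of 64 WT and 8 KO cells in the centred clustering described below. Their ratios may thus also carry a difference in shares of cells. Fatty acid oxidation genes had a median of −0.29 (percentile 0.56), with 5 of 28 lower and 1 higher, Cpt2 (0.95, 0.86 to 1.04). Of 19 suckling and weaning genes, 6 were lower, led by Amn (−3.63, −4.26 to −3.06) and Arg2 (−3.50, −4.47 to −2.67), and 1, the bile acid binding protein gene Fabp6, was higher (2.13, 1.97 to 2.29), with a median of −0.33 (percentile 3.69).

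**Figure D1:**
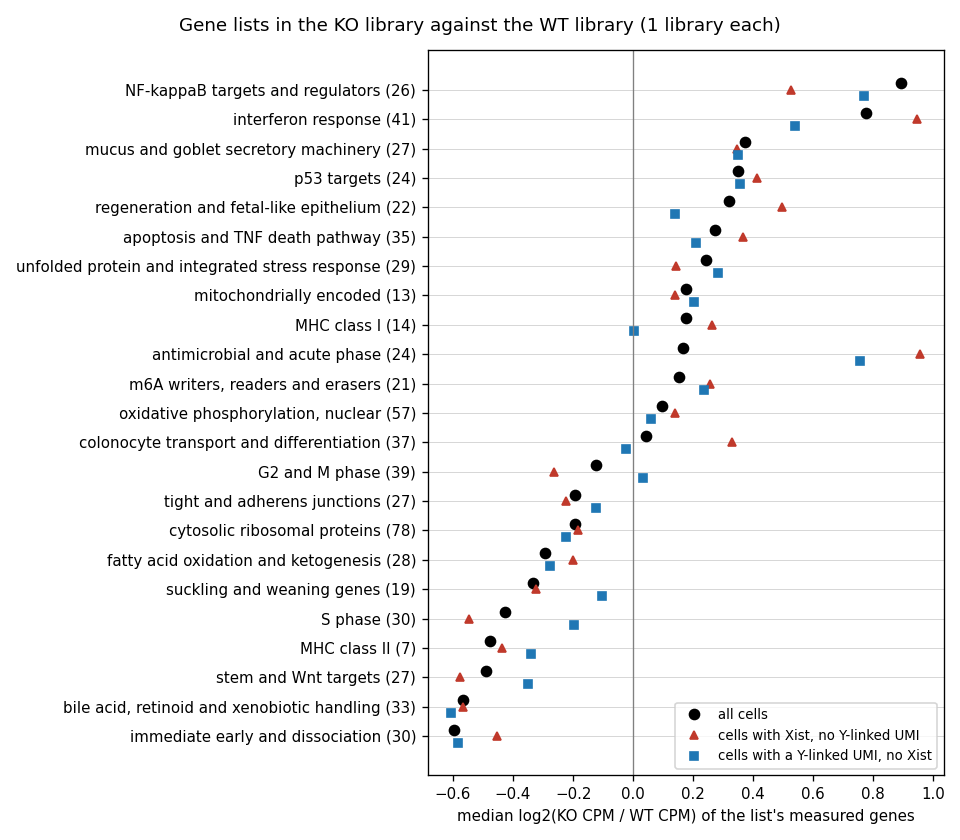
Median log2 ratio of KO over WT CPM (x axis) for each fixed gene list but the sex-linked one, with the number of measured genes in brackets (y axis), in all cells and in cells assigned to each sex by Xist and Y-linked UMIs. Of the lists drawn, NF-κB and interferon lie highest in all cells, at 0.89 and 0.78, and the immediate early list lowest, at −0.60.

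The third comparison takes the cells by class, using the authors' 7 clusters, which carry no names. By fixed markers clusters 1 and 2 were goblet-like, 3 cycling-like, 4 colonocyte-like, 5 enteroendocrine-like and 6 stromal-like. Cluster 0 (26.3% of WT and 22.3% of KO cells) scored highest for stem cell markers. It was left unnamed after the data were seen, because its leading genes were the pancreatic enzymes of the 33 cells. Without these cells Mcpt1, Ccl20, Msln and Spib led it. In a clustering centred within each library, described below, 71.3% of its WT and 52.2% of its KO cells lay in a stem-like cluster. A colonocyte-like cluster, led over both libraries together by Car1, Spib and Ccl20, held 13.7% and 28.6%. Its cells need not be alike in both, as cluster 0 had 10 WT against 570 KO UMIs of Spib. Without centring, at resolution 0.5, a cluster led by Ccl20 and Spib held 31.1% of cluster 0's KO cells and 0 of its WT cells. Another, led by Hapln1 and Reg3b, held 11.4% of the WT and 0.245% of the KO cells of cluster 0. Ratios in cluster 0 can therefore mix differences in level with differences in kinds of cells. At Leiden resolution 0.5, a cluster led by immune genes such as S100a9 and C1qa held 30 WT and 31 KO cells of cluster 0, where 5 measured immune markers had a median of 1.30. Nfkbia was higher in the KO library in each of the 5 classes compared, from 0.74 (0.29 to 1.20) in enteroendocrine-like to 1.78 (1.65 to 1.92) in colonocyte-like cells. Tnf was higher in cycling-like cells, at 111 against 18 UMIs (3.35, 2.62 to 4.15), in cluster 0, at 85 against 28 (2.48, 1.84 to 3.15), in colonocyte-like cells (2.42, 1.46 to 3.46) and in goblet-like cells (2.19, 1.28 to 3.21). Enteroendocrine-like cells had 5 Tnf UMIs against 1, a difference not detectable at this depth. Lgr5 was lower in each class, from −2.95 (−3.23 to −2.68) in cycling-like to −4.74 (−7.04 to −3.15) in enteroendocrine-like cells, where the KO library had 3 UMIs. Mki67 stood at 521 against 329 CPM in cycling-like cells (0.66, 0.61 to 0.72). The medians of the interferon, p53, apoptosis, mucus and regeneration lists were above 0 in all 5 classes, though the apoptosis median was −0.02 in goblet-like cluster 2 alone, and those of the stem and Wnt, immediate early and fatty acid oxidation lists below 0 in all 5. The NF-κB list was above 0 in 4 of them, reaching 1.37 in cluster 0, and −0.02 in enteroendocrine-like cells. Without the cells of the immune gene cluster, cluster 0 had a median of 1.38 for that list and a ratio of 2.44 (1.79 to 3.13) for Tnf. No difference between classes was tested.

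Goblet-like cells came mostly from cluster 2 in the WT library and mostly from cluster 1 in the KO library. In them Ces1c (8.18, 7.13 to 9.50), Isg15 (4.88, 4.20 to 5.65) and the vesicle GTPase gene Rab37 (4.80, 4.23 to 5.42) were highest, and Ppic (−3.82, −4.29 to −3.39), Lgr5 (−3.71, −4.33 to −3.15), Guca2a (−3.19, −3.27 to −3.12) and Fosb (−3.07, −3.29 to −2.86) lowest. Akr1c21, Slpi and Mt3 also met the rule there, but they are among the leading genes that define clusters 1 or 2. In cluster 0, Msln had 598 UMIs against 0 (at least 365-fold higher) and Plb1 199 against 0 (at least 121-fold higher), and Ncf4 (9.42, 7.56 to 12.47), Ubd (8.35, 7.50 to 9.35) and Serpina10 (6.64, 5.91 to 7.48) were higher. The genes lowest there were enzyme genes, whose UMIs lay mostly in 33 of its 1106 WT cells, and a predicted gene. The ranking within cluster 0 was not repeated without those cells. In cycling-like cells Ubd (9.67, 7.81 to 12.71), Ncf4, Slpi, Rtp4 (5.10, 4.42 to 5.87) and Serpina10 were highest. Defb50, Ang4 (−5.00, −6.22 to −4.01), the linker histone gene H1fx (−4.68, −5.64 to −3.86), Cps1 (−4.17, −4.66 to −3.73) and Gpc3 (−4.39, −5.35 to −3.57) were lowest. Over the whole WT library 98.9% of the Defb50 UMIs lay in 10 cells, so its place here rests on few cells. In colonocyte-like cells Slpi (8.44, 6.58 to 11.49), Ncf4, Ubd, Serpina10 and H2-M2 were highest, and Fosb (−3.91, −4.32 to −3.52), Timp3, Lgr5, Clu (−3.34, −3.92 to −2.82) and Atf3 lowest. Of the KO library's 5859 Slpi UMIs, 4854 lay in goblet-like cells. Whether those in other classes came from goblet cells, as free RNA or in doublets, was not tested. The numbers of genes at least 2-fold higher and lower were 335 and 206 in goblet-like cells, 580 and 197 in cluster 0, 432 and 160 in cycling-like cells, 455 and 179 in colonocyte-like cells and 381 and 245 in enteroendocrine-like cells.

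**Figure D2:**
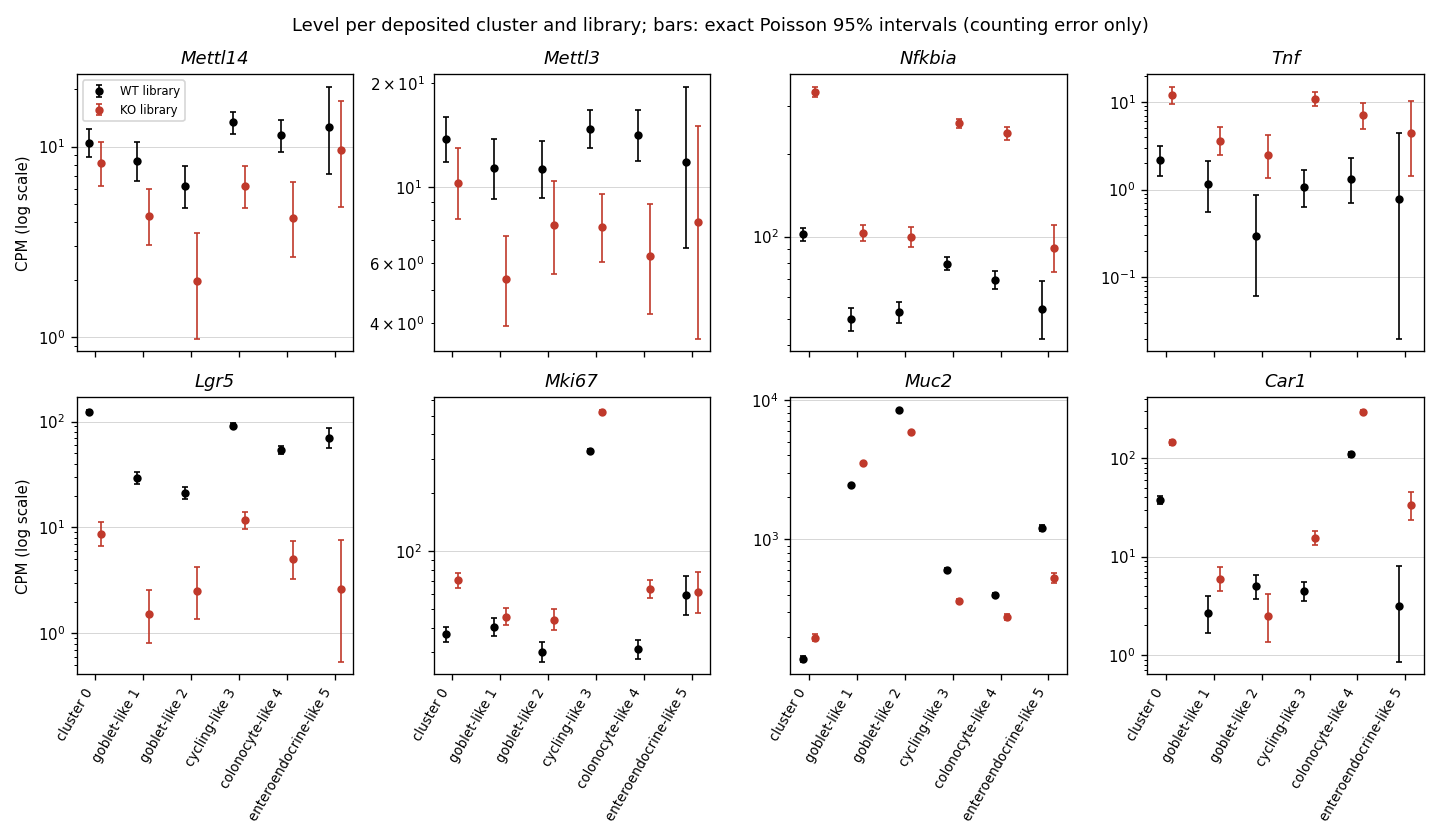
CPM (y axis, log scale) of 8 genes in clusters 0 to 5 (x axis) of the WT library (black) and the KO library (red), each point with its exact Poisson 95% interval, which covers counting error only. Nfkbia lies higher and Lgr5 lower in the KO library in every cluster drawn, while Muc2 lies higher in clusters 0 and 1 and lower in the others.

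Cell class shares could be compared only in part, because at least 6 of the 10 leading genes of every cluster but the cycling-like one differed at least 2-fold between the libraries. The gate on EpCAM and the lower depth of the KO library can also set shares. Cycling-like cells made up 24.4% of the KO library (exact interval 22.98 to 25.8) and 21.8% of the WT library (20.6 to 23.1), but 11.8% and 18.9% when thinned cells were clustered anew. A clustering chosen after seeing the data, which centred each gene within its library and left out genes at least 1.5-fold apart, was built without such genes, though its clusters were named from markers that include some of them, among them Lgr5. Setting each gene to the same mean in both libraries can also draw shares together. Similar shares under this clustering therefore do not show that the libraries were alike. In it, enteroendocrine-like cells were 3.70% of the KO library (3.11 to 4.36) and 2.33% of the WT library (1.89 to 2.83). Stem-like cells were 14.2% (13.1 to 15.4) and 21.5% (20.3 to 22.8) and colonocyte-like cells 18.0% (16.8 to 19.3) and 18.2% (17.1 to 19.4). A colonocyte-like cluster with Saa1 and Aqp8 among its leading genes held 64 WT and 8 KO cells. One led by Car1 and Spib held 208 and 265, and one led by Tgm3 held 495 and 385. Goblet-like cells were 25.4% and 28.4%, but 43.8% and 39.2% when an unnamed cluster with goblet genes such as Clca1 and Reg4 was added. The direction depends on which clusters count, and 625 of the WT and 538 of the KO goblet-like cells were in a cluster that lay mostly in the authors' cycling-like one. Tuft-like cells numbered 11 in the WT library and 0 of 3653 in the KO library, which allows a share of up to 0.0821% if the limit of a count of 0 is set at 3 cells. Stromal-like cells, which an EpCAM sort should exclude, were 0.411% (0.23 to 0.68) and 2.45% (2.001 to 2.96). The leading genes of that cluster mixed collagens with Spp1 and Pate4, so it may hold other kinds of cells. At resolution 2, clusters mostly in the authors' stromal-like one included 1 led by Col3a1 (70 WT and 10 KO cells). Others were led by Defb50 and Svs4 (29 and 0) and by Spp1 and Tm4sf4 (19 and 0). In this clustering 33.0% of KO and 22.6% of WT cells stayed unnamed, so the shares are partial.

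Cells of both sexes were present in each library. Cells with at least 3 Xist UMIs and no Y-linked UMI numbered 1689 in the WT and 1696 in the KO library, and cells with a Y-linked UMI and no Xist 1540 and 996. Xist stood at 1051 CPM in the WT and 653 CPM in the KO library. The KO library did not hold fewer cells taken as female, so their share does not give this direction. The ratio of Xist within female cells is not reported here. The fixed list of sex-linked genes had a median of −0.60 (percentile 0.71) over all cells, where the share of each sex enters too. Within male cells its 4 measured genes had a median of −0.00919. Within female cells only 1 gene of the list was measured, and no median was taken. Computed separately in the cells of each sex, the KO over WT ratios of 11544 genes correlated across genes with a Pearson r of 0.913 and a Spearman rho of 0.882, where genes are not independent replicates.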

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

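No tests of explanations were made for the results in this part, and the clusters' values were compared without a test. Of 28 genes examined for opposite directions between cell clusters with intervals that exclude equal levels, 2 showed them.

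Muc2, the gel-forming mucin, was higher in the KO library in cluster 0, with a log2 ratio of 0.50 (0.40 to 0.61), and in goblet-like cluster 1, also with 0.50 (0.48 to 0.53), where it stood at 3506 against 2471 CPM. It was lower in goblet-like cluster 2, at 5875 against 8410 CPM (−0.52, −0.54 to −0.50), in cycling-like cells (−0.74, −0.79 to −0.68), in colonocyte-like cells (−0.53, −0.62 to −0.44) and in enteroendocrine-like cells (−1.19, −1.33 to −1.05). Muc2 is among the 10 leading genes of cluster 2, so the ratios in clusters 1 and 2 depend on how the authors' clusters divide goblet-like cells. In the other 4 clusters Muc2 stood at 139 to 1211 CPM in the WT library, far below cluster 2. Free RNA was not corrected for and no doublets were removed. Whether Muc2 UMIs there came from goblet cells was not tested. The difference between clusters was not tested.

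Car1, the carbonic anhydrase gene, was higher in the KO library in cluster 0 (1.96, 1.80 to 2.11), cycling-like cells (1.80, 1.39 to 2.21), colonocyte-like cells (1.43, 1.31 to 1.54) and goblet-like cluster 1 (1.16, 0.43 to 1.94). In goblet-like cluster 2 it was lower (−0.99, −1.96 to −0.11), with 14 UMIs against 50. The difference between clusters was not tested here either.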

How the results depend on the processing

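Settings chosen after seeing the data were the separation by sex, the removal of enzyme-rich cells, of cells with UMIs of both sexes and of a cluster led by immune genes, the centred clustering and the 20 CPM minimum on a scale without mitochondrial and ribosomal-protein genes. No paired analysis was possible because each genotype has 1 library, and for the same reason leaving out each library in turn has no meaning. Removal of cells by doublet score was not run, since the score marked 0 WT cells.

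Of 27 named-gene ratios under these settings and those fixed in advance, 251 of 334 values stayed within the main counting interval, 83 moved beyond it and 0 changed sign. For the 24 lists, 161 of 167 medians stayed within the interval from resampling the list's genes. In cells with a Y-linked UMI and no Xist, 2 medians reversed, colonocyte transport from 0.044 to −0.0253 and G2 and M phase from −0.124 to 0.0342, where the cause was not tested. The largest shift of the median of all genes under another scaling was −0.07 on the log2 scale. Of 44 alternative counts of genes past 2-fold, 42 lay within 1.5 times the main count. Genes lower in all cells numbered 199 instead of 176 when mitochondrial and ribosomal-protein genes were left out of the scaling, and 299 when the 20 CPM minimum was set on that scale too, which by construction lets less abundant genes in. Genes lower in colonocyte-like cells numbered 279 instead of 179 with cells thinned to 3000 UMIs, and the cause was not tested.

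Shares of classes depended on the clustering. The goblet-like share (KO minus WT, main value 3.79 percentage points) became 28.1 with Leiden at resolution 0.5, 24.2 at resolution 2, 28.0 with thinned cells and −2.98 in the centred clustering. In each of these, clusters whose cells lay mostly in the authors' goblet-like clusters stayed unnamed, with 420 WT and 8 KO cells, 520 and 5, 446 and 8, and 456 and 672. Counted as goblet-like, they gave differences of 18.3, 12.01, 17.2 and 4.58 points. The cycling-like share (2.56) became 10.5 at resolution 0.5, where 835 of 848 such KO cells were in a cluster led by Nr1h5 and Ltb with no cycling gene among its 10 leading ones, and −7.08 with thinned cells. With unnamed clusters that lay mostly in the authors' cycling-like cluster it turned from 1.07 to −2.40 at resolution 2, and was 3.88 in the centred clustering. None of these values counts clusters that lay mostly in the authors' cycling-like one but were named Paneth-like. Such clusters held 656 WT and 12 KO cells at resolution 0.5, 163 and 4 at resolution 2, and 525 and 23 with thinned cells. The colonocyte-like share (−2.26) became 3.22 at resolution 0.5, 4.32 at resolution 2, 1.03 with thinned cells and −0.21 in the centred clustering. It became 1.76 with cells of at least 1000 UMIs and at most 10% mitochondrial UMIs, which left 1060 WT and 1176 KO cells. In the uncentred clusterings most clusters held cells of a single library, with over 90% from 1 library in 16 of 19 clusters at resolution 0.5, 32 of 38 at resolution 2 and 19 of 22 with thinned cells. For the filter on mitochondrial UMIs and the centred clustering the cause was not tested. Stem-like cells, named only in own clusterings, differed by −32.1 points at resolution 0.5, −18.03 at resolution 2, −13.5 with thinned cells and −7.31 in the centred clustering. Without stem-like clusters that lay mostly in the authors' colonocyte-like cluster, the first 3 were −21.3, −9.87 and −2.85. With own clusters put together by the authors' class that held most of their cells, whatever their name, the differences over the same 4 clusterings were 18.3, −1.94, 3.32 and 4.70 for goblet-like, −27.6, 8.23, 1.81 and 3.73 for cycling-like and 2.36, −2.53, 3.51 and −2.52 for colonocyte-like. The enteroendocrine-like share was higher in the KO library by 1.37 to 2.47 points under all alternatives run.

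Depth limits Mettl14 itself: the thinned share of cells with a UMI differed by a log2 ratio of −0.78, against −1.35 at full depth, where WT cells held more UMIs. Genes under 50 UMIs were not compared.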

Other observations

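The tests of the enzyme transcripts below were chosen only after the result was seen, and those of the immediate early genes and of exon number before. Rare cell types were unlike between the libraries. Tuft cell markers were lower in the KO library in 6 of 9 measured genes (median −2.04, percentile 0.04), with 0 against 184 UMIs of Rgs13, 2 against 144 of Sh2d6 (−5.49, −8.55 to −3.61) and 5 against 224 of the tuft cell kinase gene Dclk1 (−4.81, −6.44 to −3.56). Enteroendocrine markers were split, with 5 of 12 genes lower and 2 higher (median −0.08, percentile 38.9). Within enteroendocrine-like cells, a class with a larger share of the KO library, their median was −0.61. Over all cells, where the share of the class enters the ratios too, Tph1, the serotonin synthesis enzyme (−2.21, −2.53 to −1.91), and the hormone genes Sct (−1.88, −2.03 to −1.73) and Insl5 (−1.61, −1.74 to −1.48) were lower. Neurod1, a transcription factor of the lineage, was higher over all cells (1.59, 1.41 to 1.77). Stromal markers were lower in 8 of 9 genes (median −2.53, percentile 0), including the collagen genes Col1a2 (−3.18, −3.54 to −2.83) and Col1a1 (−3.03, −3.38 to −2.69). The medians of the remaining marker lists were −0.52 for stem cells, −0.21 for cycling cells, 0.13 for goblet cells, −0.06 for colonocytes, 0.36 for immune cells, −1.07 for endothelium, 0.40 for glia and neurons and −1.27 for Paneth cells. Of 6 erythroid markers, 1 was measured.

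None of 78 ribosomal protein genes passed 1.5-fold, and their median was −0.19 (percentile 0). Nuclear oxidative phosphorylation genes had a median of 0.10 (percentile 89.5), with 4 of 57 higher, among them Uqcrq (1.13, 1.11 to 1.15) and Uqcrfs1 (0.94, 0.91 to 0.97). Of 13 mitochondrially encoded genes, 3 were higher, led by mt-Nd2 (0.86, 0.85 to 0.87), and 1, mt-Co1, was lower (−0.71, −0.72 to −0.71), with a median of 0.18 (percentile 82.9). Junction genes were lower in 5 of 27 cases and higher in 2 (median −0.19, percentile 3.21), with Cldn2 (−1.12, −1.20 to −1.05), Cldn8 (−1.09, −1.20 to −0.98) and Cldn15 (−1.05, −1.13 to −0.98) lower and Cldn3 higher (1.04, 1.01 to 1.06). MHC class I genes were split at 4 higher and 4 lower of 14 (median 0.18, percentile 88.7), with H2-D1 higher (0.89, 0.85 to 0.92) and H2-T3 lower (−2.54, −3.04 to −2.07), in a family whose members share reads. Of 7 MHC class II genes, 3 were lower and 1, the invariant chain gene Cd74, was higher (1.12, 1.03 to 1.21), with a median of −0.48 (percentile 9.13) that was −0.08 when classes had equal weight.

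Pancreatic enzyme transcripts in the WT library may come from whole acinar cells that entered the sort. Of the 11 enzyme genes' UMIs, 99.4% lay in 33 cells in which they made up a median of 30.7% of the UMIs, and Ctrb1 alone stood at 75290 CPM in them. Free RNA taken up by all droplets is argued against, because the enzyme level outside these cells was 8.87 CPM, or 0.638% of the all-cell level. Expression by colonic epithelial cells is argued against by Cdx2, an intestinal transcription factor, whose log2 ratio in these cells against the other WT cells of cluster 0 was −3.63 (−4.95 to −2.59). How they entered the sort stays open. Epcam, the antigen of the gate, stood at 654 CPM in them against 1638 in the others.

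Genes with few coding exons were higher in the KO library relative to genes with many. The median log2 ratio was 0.25 for 776 genes with 1 coding exon, 0.26 for those with 2 to 3, 0.06 with 4 to 6, −0.04 with 7 to 9 and −0.14 for 5497 genes with at least 10, a difference between the extremes of 0.39 (0.31 to 0.47 by resampling genes). It lay between 0.40 and 0.55 in each cluster with at least 50 cells per library and in each sex. Genes with 1 coding exon also spread more to both sides. Of them 20.6% were at least 2-fold higher and 10.95% at least 2-fold lower, against 3.97% and 6.93% of those with at least 10. Adjusting for transcript length, GC content and level left 110.9% of the all-cell difference (100.8 to 122.5), and weighting the classes equally left 101.3% (91.7 to 110.0), so neither accounts for it. The pattern is what a gain of RNA from transcripts with few exon junctions in KO cells would give, and a candidate explanation is that m6A, which is excluded near exon junctions and marks transcripts for decay, was reduced there. This is a hypothesis from 1 library per genotype that m6A maps or RNA decay rates, which were not measured, would test, and a difference in library preparation or RNA quality that acts on such transcripts stays open.

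Immediate early genes, which tissue dissociation induces, were lower in the KO library in every cluster with at least 50 cells per library. They were lower in the cells of both sexes too, and these medians ranged from −0.87 to −0.45. That uniformity is what handling that differed between the preparations would give, and with 1 preparation per genotype it was not separated from an effect of the genotype. A single animal of a pooled library is argued against, because the sex with the smaller difference still had a median of −0.45. Over 200 resamplings of its cells the values ranged from −0.65 to −0.32, which does not cover spread between animals. The list's median after every cell was thinned to the same depth was −0.64, with a range of −0.81 to −0.47 over as many resamplings. This value cannot decide whether lower depth plays a part. Thinning leaves each gene's expected share of a cell's UMIs unchanged and alters only the weight of each cell in the CPM. Fosb, Atf3 and Cyr61 belong to this list, and their ratios carry the same doubt.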
